A study of Mus musculus with 8 samples.

How the data were processed

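Poly(A) RNA from cultured mouse cardiac fibroblasts was sequenced, per the labels, from 4 cultures given a control adenovirus carrying GFP and 4 given an adenovirus carrying Has2. Libraries were made with a strand-specific mRNA kit, per the labels' protocols. The authors deposited raw counts per Ensembl gene for the 8 libraries in a single table with no summary lines. Per the submitters' processing notes, reads were checked with FastQC 0.10.1, counted with HTSeq 0.10.0, and the mouse build was mm39 (GRCm39). The aligner, the annotation release and the strand setting are not given in the sources used here. Reads of overlapping, antisense or near-identical genes can therefore have been divided in a way that is not known here. The virus may deliver a transcript counted as Has2, so Has2 counts hold endogenous and viral transcripts together.

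The table lists 55414 genes. Symbols were matched by Ensembl identifier to GENCODE M21, which annotates an older mouse build; 52081 identifiers matched and 3333 did not. Identifiers without a symbol held 0.405% to 0.871% of the counts of a library and stayed in the tests. No coordinates are given, because the reference at hand and the deposited counts are on different builds. GENCODE M21 also supplied the GC content and length of the longest transcript of each gene, which were available for 99.8% of the genes tested.

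Libraries held 46981231 to 55795187 counts. Without a block the median standard error of a log2 fold change was 0.23, and 11394 of the 15150 genes tested had a 95% interval within 2-fold in either direction. Exact binomial intervals of shares cover counting error only, since reads without molecular identifiers are not independent molecules. Within groups no 2 libraries agreed within sampling noise: chi-square over degrees of freedom was 41.8 to 333.

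Groups came from the labels, and replicate numbers from the sample titles. Libraries of the same number in both groups also carry the same preparation identifier in their names. The numbers pair the libraries: the deviations from the group means correlated at 0.58, 0.62, 0.53 and 0.44 between libraries of replicates 1, 2, 3 and 4. Replicates 1 and 2 are female and replicates 3 and 4 male, and the preparation identifiers of the sexes start with different letters, so sex and preparation series cannot be told apart. The labels call the genotype wild type, whereas the protocol text names animals with a floxed Has2 gene. That protocol also mentions a Cre virus, which is not analysed here.

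The main test was edgeR 4.0.16 (R 4.3.3) with the quasi-likelihood F-test, TMM scaling, the default expression filter and group as the only term, called at a Benjamini-Hochberg adjusted p under 0.05. The interaction of sex and virus was tested in the same way, and again with the replicate number as a block. Gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 between genes, on voom log2 CPM values and without Has2, adjusted over the 44 lists with at least 3 tested members out of 49 lists. Camera with an estimated correlation and fry were run beside it. List scores are the mean log2 CPM, with a pseudocount of 2, and were compared with two-sided exact permutation tests; 4 libraries against 4 cannot give a p below 0.0286, and 4 pairs cannot give one below 0.125.

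Lists, tests, alternatives and the rule for named genes were fixed before the data were examined. The rule names Has2, Has1 and Has3, then up to 8 called genes per direction with a mean of at least 5 CPM and the same direction in all 4 pairs, then up to 4 members with the smallest p of each described list and any member of the hyaluronan lists. For the interaction it names up to 5 genes with the smallest p per direction, and for checks Xist and Y-linked genes. Genes outside the rule are marked where they appear.

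Set at the same time were these other ways of processing: the replicate block, sex as a covariate, other scalings (RLE, library totals, scaling without Has2 counts), other expression filters, leaving out each library and each replicate number, DESeq2 1.42.0 with and without the block, limma-voom, stricter thresholds and the other list tests. Chosen after seeing the data were fits without both male Has2 libraries, fits within each sex, list tests of the interaction, list tests with an estimated correlation on corrected values, and a correction that removed a spline trend (5 degrees of freedom each) of GC content and log2 transcript length from every library.

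The tests were tried on simulated counts with the real means and spreads and 200 changed genes. For the virus comparison over 15005 genes, 0 of 67 genes changed 1.5-fold were called, 31.3% of 67 changed 2-fold and 90.9% of 66 changed 4-fold. With the replicate block over 15021 genes the shares were 31.3%, 85.1% and 66 of 66 genes. For the interaction over 14945 genes the shares were 0%, 1.49% and 33.3%, and with the block over 14991 genes 41.8%, 77.6% and 98.5%. Unchanged genes made up 6.90%, 7.69%, 14.8% and 9.38% of the calls in these 4 simulations. In a simulated interaction made only of a GC and length trend, 1016 of 14996 genes were called before the correction and 1 after it. That trend was taken from the fit to the male Has2 libraries, put into those libraries only and removed with the same model. Its fall was therefore fixed in advance. With the interferon list lowered by a log2 change of -0.65 and all other genes unchanged, camera, camera with an estimated correlation and fry each called that list and 0 of the others. Genes were simulated independently, whereas the estimated correlation in the data was 0.21 for the interferon list and 0.54 for the G2 and M list. The simulation therefore could not show false list calls, or lost ones, from genes that vary together.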

Results

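Cardiac fibroblasts, the stromal cells that build the matrix of the heart, were grown from mouse hearts and infected at passage 2 with an adenovirus for Has2 or for green fluorescent protein (GFP). Has2 encodes hyaluronan synthase 2, a plasma membrane enzyme that makes hyaluronan, a large unsulfated polysaccharide of the extracellular matrix. The cells had been starved of serum for 24 h, were exposed to virus for 5 h, and were collected after a further 48 h in medium for which the protocol lists basic FGF and TGF-beta at 20 ng/mL. Each virus had 4 libraries, 2 from females and 2 from males, and the comparison asks which transcripts change when these cells are made to express Has2. Total counts ran from 46981231 (GFP replicate 1) to 55795187 (Has2 replicate 1). The labels do not say whether the cultures came from separate animals, so p values measure only the spread between these samples.

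Has2 rose strongly in every culture given its virus. The Has2 transcript (ENSMUSG00000022367) stood at 18.02 ± 7.65 CPM (counts scaled by effective library size; SD, n = 4) with the GFP virus and at 6502 ± 2964 CPM (SD, n = 4) with the Has2 virus. Its log2 fold change was 8.49 (SE 0.57; 95% interval 7.21 to 9.78; edgeR adjusted p = 0.0011), and 8.46 with the replicate block (edgeR adjusted p = 0.0226). Within the pairs of replicates 1, 2, 3 and 4, Has2 was 379, 1142, 176 and 229 times as high with its own virus. Its share of all counts was 0.951% in Has2 replicate 1 (exact binomial 95% interval 0.948% to 0.953%), 0.807% in replicate 2, 0.318% in replicate 3 and 0.503% in replicate 4. In the GFP libraries this share did not exceed 0.00254%. An exact permutation test of the group means of log2 CPM gave p = 0.0286, the smallest it can give. The paired exact test gave p = 0.125, also the smallest it can give with 4 pairs.

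**Figure D1:**
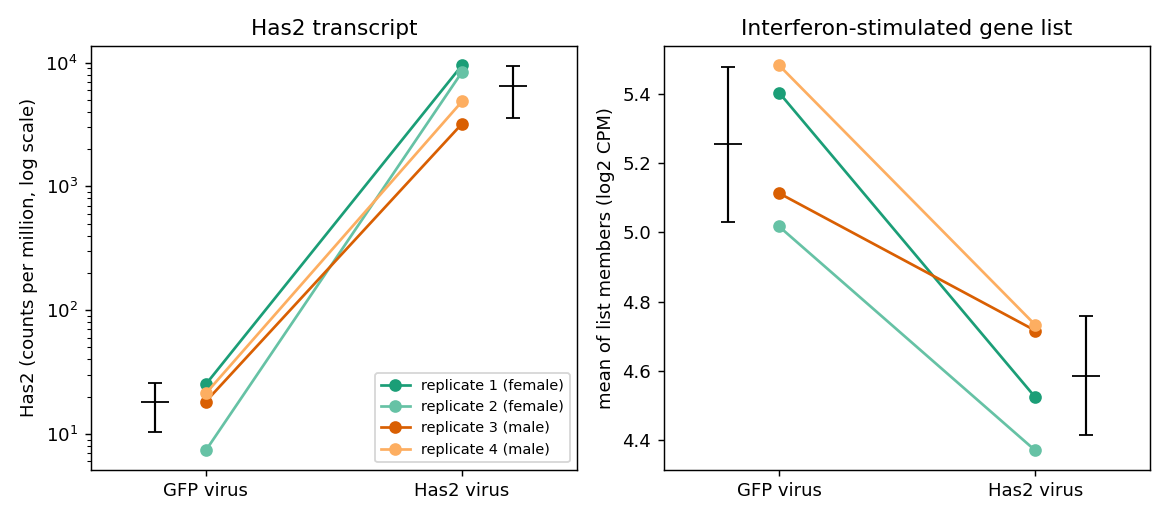
Has2 (left, CPM on a log axis) and the mean of the 62 interferon-stimulated genes (right, log2 CPM) in each library; lines join libraries of the same replicate number, and black marks show the mean and SD of 4 libraries. Has2 lies between 3209 and 9533 CPM in the Has2 virus libraries and at or below 25.2 CPM in the others, and the interferon mean is lower with the Has2 virus in all 4 pairs.

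Beside Has2 itself, 0 of 15150 genes passed edgeR's quasi-likelihood test at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 388 genes, 68 higher and 320 lower with the Has2 virus, where 757.5 would lie by chance. With the replicate block there were 1134 (390 higher, 744 lower), with the GC and length trend removed 364 (147 higher, 217 lower), and with both 1594 (867 higher, 727 lower), so the balance towards lower values turned. The test without the block leaves out the pairing, and its median standard error of a log2 fold change was 0.23, against 0.14 with the block. Its count below 757.5 is therefore not a sign of less change than chance gives. Nor is the 1134 with the block a sign of more. Of the 8 splits of the libraries that part every pair, 3, the real one included, held at least as many. limma-voom also called 1 gene. DESeq2 called 7, namely Has2 higher and Ifit3b, Ifi44, Gbp3, Ifit3, Nmi and Rsad2 lower; Nmi and Rsad2 were named after their values were seen. Of these 6 lower genes 5 belong to the interferon list; Nmi does not, and its log2 fold change was -0.65 (SE 0.13), or -0.41 with the GC and length trend removed. With the replicate block DESeq2 called 61 genes, 13 higher and 48 lower, of which 19 belong to the interferon list.

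Of the other genes of hyaluronan metabolism 0 passed the test, over all genes or adjusted over each list alone. Has1, a second synthase, was measured at 3.72 ± 1.79 CPM with the GFP virus and 3.41 ± 2.61 CPM with the Has2 virus (SD, n = 4; log2 fold change -0.13, SE 0.65), and Has3 had only 2 to 11 counts per library, too few for the test. In the blocked fit with sex, which called 4470 genes, Has1 was at -0.98 in female and 0.18 in male pairs. The edgeR adjusted p of this difference was 0.0078, and 0.0221 with the GC and length trend removed. Has1 was not alone in this. Ugp2, Tlr4 and Vcan also differed in that fit (edgeR adjusted p = 0.000185, 0.000401 and 0.00194), but not with the trend removed (0.25, 0.277 and 0.981). Hmmr was called in both (0.00065 and 0.0484). Tnfaip6 and Ugdh were called only with the trend removed (0.00488 and 0.00548). Of the 12 genes that supply the sugar precursors, Uap1, which makes UDP-N-acetylglucosamine, had a log2 fold change of -0.23 (SE 0.11), and Ugdh, which makes UDP-glucuronic acid, -0.27 (SE 0.15); both were lower in all 4 pairs. The medians were 0.01 for these 12 genes, 0.06 for 8 turnover genes and -0.02 for 16 receptors and binding proteins. Camera's adjusted p values were 0.91, 0.45 and 0.51, and the mean of the precursor genes (-0.04) and the test direction of the binding proteins (up) differ in sign from the median. Among turnover genes, the hyaluronidase Hyal1 had a log2 fold change of 0.40 (SE 0.25), Hyal2 0.14 (SE 0.20) and the hyaluronan depolymerase Cemip 0.39 (SE 0.75). The binding proteins of smallest p were expressed at low levels: Itih3, whose product is a hyaluronan-linked serum protein chain, had a log2 fold change of -2.42 (SE 1.28), Bcan 0.74 (SE 0.39) and Hapln4 0.58 (SE 0.40), the last 2 higher in 4 of 4 pairs. Itih3 was at 4.01 CPM in GFP replicate 1 and at or below 0.438 CPM in the other GFP libraries, and its log2 fold change was 0.34 without that library. The receptor Cd44 was at 228 ± 27.0 CPM and 233 ± 40.2 CPM with the GFP and Has2 viruses (SD, n = 4), Tnfaip6 had a log2 fold change of -0.17 (SE 0.16) and the hyaluronan-binding proteoglycan Vcan -0.03 (SE 0.22). Without Has2 replicate 2 the value of Cemip was -0.35 and that of Has1 0.23, and without Has2 replicate 3 that of Hyal2 was -0.02; Cd44 and Vcan also changed sign when single libraries were left out, and Tnfaip6 was at 0.24 and Ugdh at -0.01 with the GC and length trend removed. Hyal1 was at 0.16 without Has2 replicate 2 and Hapln4 at 0.22 without Has2 replicate 4.

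Interferon-stimulated genes, the antiviral program switched on by interferon receptors, were lower with the Has2 virus. Of the 62 measured members 60 had a negative fold change, 16 fell when adjusted over the list alone, 0 did over all genes tested, and 45 were lower in all 4 pairs. The median log2 fold change was -0.65, a level 1.57 times lower. Ifit3b went from 60.7 ± 11.5 to 28.1 ± 2.99 CPM (SD, n = 4; log2 fold change -1.11, SE 0.16), and Ifi44 from 86.8 ± 23.0 to 35.7 ± 5.32 CPM (-1.28, SE 0.20). The GTPase Gbp3 had a log2 fold change of -1.11 (SE 0.19) and Ifit3 one of -1.02 (SE 0.18); the edgeR p of all 4 genes was 0.0032 adjusted over the list alone. Ifit3 and Ifit3b are close copies, so reads may have been split between them. With the replicate block 50 of the 62 members fell, adjusted over the list alone.

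Camera called the interferon list (adjusted p = 7.43e-44), but with an estimated correlation its adjusted p = 0.129 (unadjusted p = 0.0029), and fry gave an adjusted p = 0.1. The list mean was 5.25 ± 0.22 log2 CPM with the GFP virus and 4.59 ± 0.17 with the Has2 virus (SD, n = 4), lower in 4 of 4 pairs. The exact permutation test gave p = 0.0286 and the paired one p = 0.125, each the smallest possible. Adjusted over the 44 lists the first is 1, as for any list alone at that floor, so the adjusted value does not bear on the change. The male pairs, in which the changes of all genes followed transcript GC content, had a median of -0.47 in this list and the female pairs -0.76. Markers of macrophages, which these cultures also held, had a median of 0.06 over 17 genes, with -0.16 in the female and 0.18 in the male pairs.

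Inflammatory genes driven by NF-kappaB gave a mixed picture. Over 36 measured members the median was 0.00 and the mean -0.10, camera's direction was down with an adjusted p = 0.623, and 0 members passed over the list alone. The chemokines Ccl5 (log2 fold change -1.08, SE 0.32) and Ccl7 (-0.67, SE 0.27) were lower in 4 of 4 pairs, and the cytokine Il6 (-0.73, SE 0.35) in 3. Il6 was at -0.05 in female and -1.43 in male pairs, and at -0.42 without replicate 4; removal of the GC and length trend left it at -0.37 and Ccl7 at -0.32. With the replicate block 2 members were called lower over the list alone.

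Matrix glycoproteins and contractile genes of myofibroblasts, the activated state of fibroblasts, had small positive medians. In the matrix glycoprotein list 24 of 30 members had positive fold changes, with a median of 0.14, and camera called the list up (adjusted p = 0.005; adjusted p = 0.875 with an estimated correlation). Fibronectin (Fn1) was at 4845 ± 1004 CPM and 6666 ± 1821 CPM with the GFP and Has2 viruses (SD, n = 4; log2 fold change 0.46, SE 0.23), fibrillin-1 (Fbn1) had a log2 fold change of 0.24 (SE 0.13), Lama2 0.37 (SE 0.20) and osteopontin (Spp1) -0.53 (SE 0.33). In the contractile list 20 of 23 members had positive fold changes, with a median of 0.10, and camera called it up (adjusted p = 0.0417; adjusted p = 0.41 with an estimated correlation). Its members of smallest p were Itga11 (0.38, SE 0.28), Mylk (0.30, SE 0.23), Smtn (0.22, SE 0.17) and Myh9 (0.15, SE 0.12). None of the members of these lists passed over the list alone. Without Has2 replicate 2 Fn1 was at 0.31, Lama2 at 0.21 and Itga11 at 0.11, and without Has2 replicate 1 Mylk was at 0.20 and Spp1 at -0.35. Removal of the GC and length trend left Fbn1 at 0.15, Spp1 at -0.21, Smtn at 0.12 and Myh9 at 0.04.

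The collagen list was not called (19 genes, median 0.08, camera adjusted p = 0.285), and its members of smallest p were Col12a1 (0.57, SE 0.45; 0.13 without Has2 replicate 2) and Col4a2 (0.14, SE 0.15; 0.01 without replicate 3 and 0.03 with the GC and length trend removed). Chosen after their values were seen, the smooth muscle actin Acta2 had a log2 fold change of 0.09 (SE 0.21), Col1a1 0.02 (SE 0.19), Col3a1 0.06 (SE 0.31) and periostin (Postn) -0.36 (SE 0.41); the signs of Acta2, Col1a1, Col3a1 and Postn changed in some of the alternatives.

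Genes of the G2 and M phases of the cell cycle were mostly lower with the Has2 virus. Of 44 members 40 had negative fold changes and the median was -0.14 (camera down, adjusted p = 0.000782; adjusted p = 0.875 with an estimated correlation), and 0 passed over the list alone. Only 3 members were lower in all 4 pairs. The list mean was lower in 3 pairs and slightly higher in that of replicate 1 (0.03), with an exact permutation p = 0.286. Hmgb2 had a log2 fold change of -0.43 (SE 0.19), the spindle checkpoint kinases Bub1 and Ttk -0.74 (SE 0.41) and -0.60 (SE 0.34), and the kinetochore gene Ndc80 -0.54 (SE 0.31). The median was -0.26 in the male pairs and -0.08 in the female pairs, and these genes have a median GC content of 46.3%. The list was still called with the GC and length trend removed, without and with the replicate block (adjusted p = 0.00494 and 0.00105; medians -0.11 and -0.12; adjusted p = 0.992 and 0.952 with an estimated correlation), while without the block Hmgb2 was at 0.00, Bub1 at -0.46, Ttk at -0.37 and Ndc80 at -0.30. Without GFP replicate 4 these 4 genes were at -0.28, -0.44, -0.33 and -0.32. Bub1 and Ndc80 were at 0.05 and 0.07 in females alone.

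These 3 smaller list calls depended on single libraries. Without GFP replicate 4 the cell cycle list had a median of 0.02, turned in sign (adjusted p = 0.478), the matrix glycoproteins one of 0.10 (adjusted p = 0.0732) and the contractile genes one of 0.13 (adjusted p = 0.0732). Without Has2 replicate 2 the medians were -0.04 for the cell cycle list (adjusted p = 0.376) and 0.00 for the matrix glycoproteins (adjusted p = 0.359). The contractile genes had medians of 0.18 and 0.05 without Has2 replicates 1 and 3 (adjusted p = 0.158 and 0.147). With the GC and length trend removed, the contractile genes were not called without or with the replicate block (adjusted p = 0.244 and 0.0685), and the matrix glycoproteins were not called without the block (adjusted p = 0.141; median 0.10 against 0.14) but were called with it (adjusted p = 0.00998; median 0.09; adjusted p = 0.952 with an estimated correlation).

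**Figure D2:**
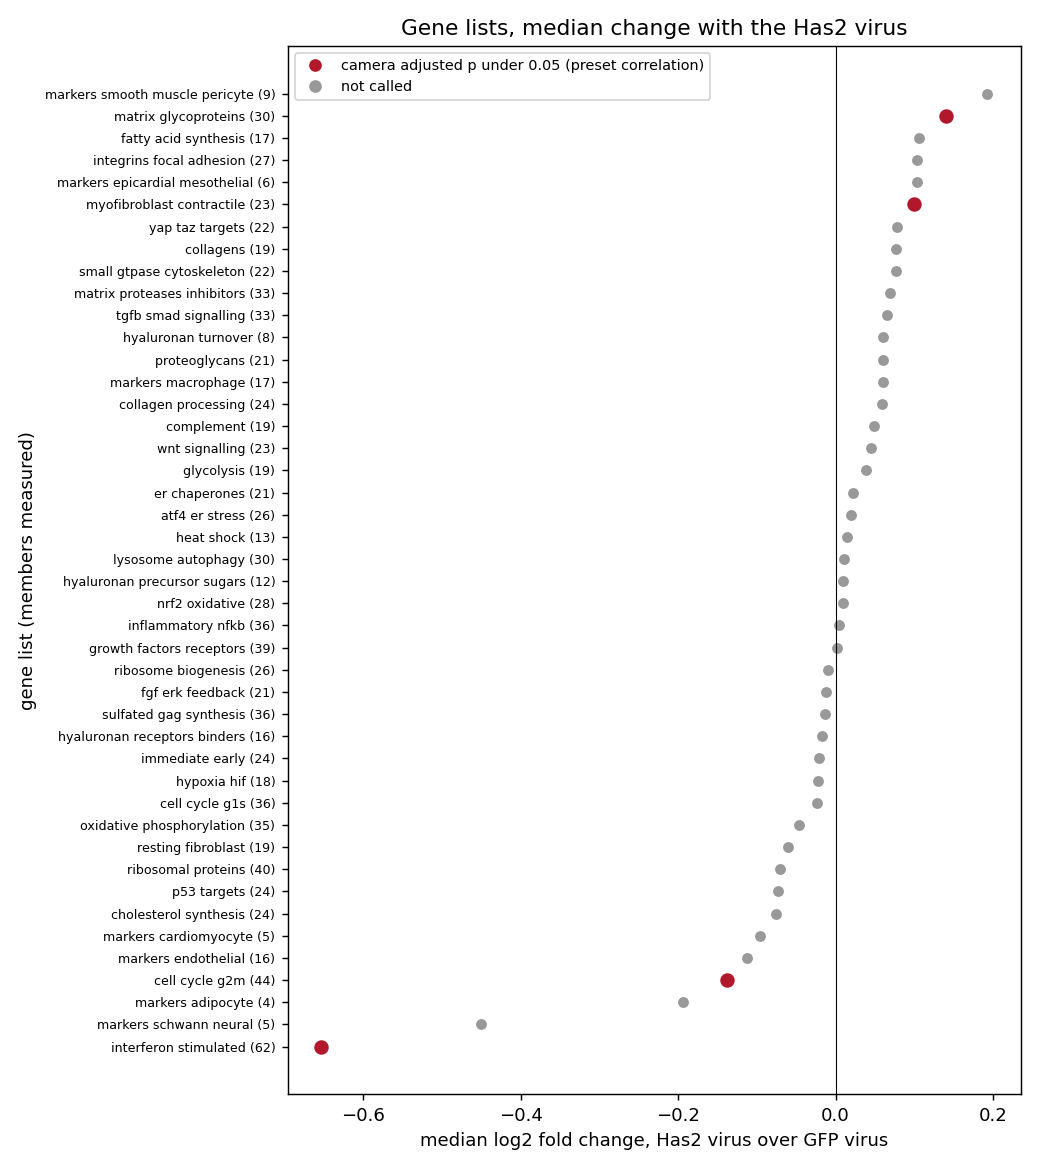
Median log2 fold change (Has2 virus over GFP virus, horizontal axis) of the 44 gene lists tested (vertical axis, with the number of members measured); red points passed camera with the preset correlation, grey points did not. The interferon-stimulated list lies at -0.65, and the other 3 called lists lie between -0.14 and 0.14.

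The labels give the sex of each culture, so the response to the virus was compared between male and female pairs. Genes with a more negative fold change in female pairs were led by the interferon-induced Isg15 (log2 fold change -1.44 in females and -0.22 in males), Oas1a (-1.23 and -0.07) and Usp18 (-1.37 and -0.25), with Bok (-0.81 and 0.26) and AI413582 (-0.75 and 0.22). In the other direction stood Ogn, a small leucine-rich proteoglycan (0.26 in females and -1.48 in males), the cGMP-dependent kinase Prkg1 (0.60 and -1.13), Zfp445 (0.18 and -1.38), Zfp68 (0.02 and -1.42) and Mpp5 (0.22 and -1.30). Has2 itself had a log2 fold change of 9.30 in females and 7.65 in males; without the block its difference was -1.43, or -2.64 and -0.80 without GFP replicates 1 and 2. The values per sex come from the blocked fit, with 2 pairs per sex. With the GC and length trend removed from that fit the differences, male minus female, were smaller: 0.80 for Isg15, 0.87 for Oas1a, 0.85 for Usp18, 0.61 for Bok and 0.55 for AI413582 (1.23, 1.16, 1.12, 1.08 and 0.97 before). They were -0.74 for Ogn, -0.79 for Prkg1, -0.83 for Zfp445, -0.56 for Zfp68 and -0.49 for Mpp5 (-1.74, -1.74, -1.56, -1.44 and -1.51 before), genes whose GC content is 36.3% to 43.3%. All 10 were still called, with edgeR adjusted p values of 0.00257 to 0.032.

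How many genes differ between the sexes in their response rests on the pairing. Without the block edgeR called 0 of 15150 genes for the interaction (2014 at an unadjusted p under 0.05), while with the replicate block it called 4470, 1748 with a higher fold change in males and 2722 with a lower one; for this sex by virus interaction DESeq2 without the block called 634. The 10 named genes had edgeR adjusted p values of 0.15 to 0.164 without the block and of 3.86e-05 to 0.00128 with it. The male changes followed transcript GC content: across genes, which are not independent replicates, Spearman's rho between the change and GC was 0.66 and 0.64 in the male pairs and -0.22 and -0.17 in the female pairs. Between the change and transcript length rho was 0.25 and 0.49 in the pairs of replicates 1 and 2, which are female. It was -0.097 and -0.36 in those of replicates 3 and 4, which are male. With the GC and length trend removed from the blocked fit 1610 genes were called, 899 higher and 711 lower; 1032 genes were called in both fits, 990 of them in the same direction.

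Among the lists, ribosomal proteins and oxidative phosphorylation had the smallest camera p for the difference between the sexes. The 40 ribosomal protein genes had a median log2 fold change of -0.42 in female and 0.23 in male pairs, and the 35 genes of oxidative phosphorylation -0.28 and 0.17. The share of mitochondrially encoded transcripts was higher with the Has2 virus in both female pairs (1.02% and 1.88%, 0.662% and 0.909%, with the GFP and Has2 viruses) and lower in both male pairs (0.702% and 0.417%, 0.94% and 0.603%). Camera called 6 lists for the interaction, all higher in males: these 2, glycolysis (medians -0.17 and 0.26), the ATF4 stress response (-0.11 and 0.22), NRF2 targets (-0.05 and 0.16) and the interferon-stimulated genes. With an estimated correlation 0 lists were called (adjusted p = 0.952 for the interferon list). With the replicate block 7 lists were called, the macrophage markers in addition, but 0 with an estimated correlation. With the GC and length trend also removed the ATF4, NRF2 and macrophage lists were not called (adjusted p = 0.372, 0.214 and 0.372); the other 4 of the 7 were, with cholesterol synthesis higher (adjusted p = 0.00138) and p53 targets lower in males (adjusted p = 0.00842), and again 0 with an estimated correlation (adjusted p = 0.925 for each).

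**Figure D3:**
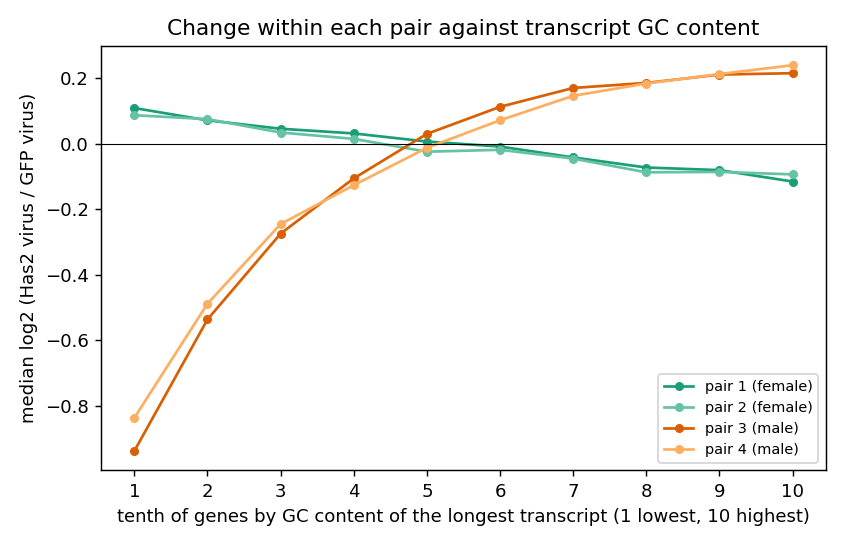
Median log2 change (Has2 virus over GFP virus, vertical axis) within each of the 4 pairs, for deciles of the genes ordered by the GC content of their longest transcript (horizontal axis). In the decile with the lowest GC the male pairs lie at -0.94 and -0.84 and the female pairs at 0.11 and 0.09.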

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

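The tests of GC content, of Has2 levels and of macrophage markers below were chosen after the results were seen; the other splits of the libraries and the question of the virus preparations were set before.

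The response to the virus differed between male and female pairs in the blocked fit, with 4470 genes called. Higher in males were Isg15 (log2 difference, male minus female, 1.23), Oas1a (1.16), Usp18 (1.12), Bok (1.08) and AI413582 (0.97). Lower in males were Ogn (-1.74), Prkg1 (-1.74), Zfp445 (-1.56), Mpp5 (-1.51), Zfp68 (-1.44) and Has2 (-1.66). With the GC and length trend removed the differences of the named genes other than Has2 were 0.55 to 0.87 and -0.83 to -0.49.

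A bias of the fitted form in transcript GC content and length is argued against as the whole cause of this difference. With that trend removed 1610 genes were called, of which 990 had been called in the same direction before (578 had not been called). A simulated trend left 1, but it had the fitted form and was removed with the same model, so this was fixed in advance. Before removal the simulated trend gave 1016 calls. It was put into the male Has2 libraries only, whereas the other libraries had trends of their own. That count therefore cannot be set against the 4470 in the data. A bias of another form is not excluded. As part of the cause such a bias has the values it needs: the trend took 46.2% of the variance of the interaction across genes. A response that itself varies with GC content would give such a share too. Has2 lost its own interaction call with the trend removed (log2 difference -0.84 with SE 0.39 against -1.66 with SE 0.38). Its correction used the longest mouse transcript, and the sequence delivered by the virus is not known, so this value does not bear on bias. A different Has2 level cannot be told apart from sex, because Has2 reached 8406 and 9533 CPM in females and 3209 and 4860 CPM in males, with no overlap (the difference of -1.66 above). Of the 3 ways to divide the 4 pairs into 2 and 2, only the division by sex (1 of 3) called any gene, against 0 for both others, but 3 divisions are too few for a share under 0.05. Sex and preparation series remain open and untested.

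The fall of the interferon-stimulated genes was weighed against several explanations. With the GC and length trend removed in the blocked fit the median of the list was -0.55 (camera adjusted p = 2.84e-44; adjusted p = 0.952 with an estimated correlation, against 0.885 before the correction), which argues against that trend as the whole cause, though the list is not called with an estimated correlation in either fit. Fewer macrophages in the Has2 cultures would lower their markers together, but the lower quartile of 17 macrophage markers was -0.16 (median 0.06, upper quartile 0.11), 0 of them lay at or below -0.65, and the abundant Lyz2, chosen like C1qa after its values were seen, (969 ± 304 and 1022 ± 317 CPM, SD, n = 4, with the GFP and Has2 viruses) and C1qa (220 ± 76.5 and 230 ± 106 CPM) were at like levels, with log2 fold changes of 0.08 and 0.06 whose signs changed in some alternatives. A difference between the virus preparations other than Has2, such as the infecting dose, cannot be told apart from an effect of Has2, since 0 libraries lacked a virus. An effect of Has2 or of hyaluronan on the interferon program may therefore be put forward only as a hypothesis.

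Other splits of the 8 libraries into 4 and 4 bear on both counts. For genes, 5 of the 35 splits, the real one included, called at least 1 gene, so chance is not excluded for a count of 1. The 1 gene of the real split was Has2, which its virus delivers, so the splits cast no doubt on that gene. Beside Has2 the real split called 0 genes. The highest of the others called 225, and the split by sex called 213, which points to structure among the libraries. The split with 225 set GFP replicates 1, 3 and 4 and Has2 replicate 1 against the rest. Spearman's rho between a library's deviation from the gene means and transcript GC was -0.467 to -0.138 in those libraries. In the rest it was -0.0605 to 0.632. Among the 8 splits that part all 4 pairs the real split alone called a gene (1 against 0 for the highest other, with or without the block). That gene was again Has2, so this outcome was fixed by the design and says nothing about chance for other genes. At an unadjusted edgeR p under 0.05 with the block the real split held 1134 genes. In 3 of these 8 splits, the real one included, there were at least as many, with 3878 in the highest other. Chance is thus not excluded for that count. For lists, 32 of 35 splits called at least 4, with 21 in the highest other, so chance is not excluded for the count of 4 lists. With the block 7 of the 8 splits that part all 4 pairs called at least 4, with 14 in the highest other. The interferon list was called in 22 of the 35 splits, and in 2 of them, the real one included, with an adjusted p as small.

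Single libraries lay far from the rest of their group in 5 of 130 groups of 4 libraries looked at, where chance alone would give about 5%. Spp1 was at 3075 CPM in Has2 replicate 1 and at 5077 to 5408 CPM in the other Has2 libraries. Itga11 was at 200.02 CPM in Has2 replicate 2 and at 103 to 117 CPM in the others. Prg4 was at 16.7 CPM in GFP replicate 2 against 11.6 to 12.2 CPM, and Cryab at 208 CPM in the same library against 164 to 165 CPM. Itih3 was at 4.01 CPM in GFP replicate 1 and at 0 to 0.438 CPM in the other GFP libraries.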

How the results depend on the processing

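The tests within a sex, without both male Has2 libraries, with the GC and length correction, with that correction and an estimated correlation, and of lists for the interaction were chosen only after the results were seen.

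Has2 kept its direction in all alternatives and lost its call only within females alone (log2 fold change 9.12, edgeR adjusted p = 0.799). The fit within males, also of 2 libraries per virus, called it (7.68, edgeR adjusted p = 0.000211). Sample number alone thus does not account for the loss. Outside females alone the log2 fold change of Has2 ranged from 7.68 to 8.96. The interferon list was called down in every fit with the preset correlation, with medians of -0.83 to -0.49, but not with an estimated correlation (adjusted p = 0.129, and 0.885 with the block) or with fry (adjusted p = 0.1). The count of changed genes, 1 without a block, was 2 without both male Has2 libraries (Has2 and Isg15), 0 in females alone, 1415 in males alone (3 higher, 1412 lower; neither of these fits uses the pairing), 2 with the GC and length correction and replicate block (Has2 and Gbp3), 7 with DESeq2 and 61 with DESeq2 and the block; it was 1 to 1 when single libraries or replicates were left out, and 1 with the replicate block alone. With the pairing, the blocked fit of all libraries called 1095 genes in females (364 higher, 731 lower) and 3765 in males (860 higher, 2905 lower). The cause was not tested. DESeq2 gave no adjusted p for 252 genes, and for 10362 with the block.

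The count of lists, 4 with or without the replicate block, was 11 without both male Has2 libraries, 8 in males alone, 6 in females alone, 6 with no low-count filter, 3 with library totals only or a mean of at least 5 CPM, 2 with the GC and length correction, 3 with that correction and the block, 0 with an estimated correlation (also with the block, with the correction, and with both) and 0 with fry; leaving out single libraries or replicates gave 4 to 14, the highest without Has2 replicate 4, with 10, 9 and 7 without GFP replicate 1, GFP replicate 2 and Has2 replicate 3. The interaction count, 0 without a block, was 4470 with the replicate block, 634 with DESeq2, 1610 with the GC and length correction and block, and 0 to 4 when single libraries were left out (4 without GFP replicate 2). The interaction lists, 6 without a block, were 7 with it, 6 (5 higher, 1 lower in males) with the correction and block, and 0 with an estimated correlation in each of these 3 fits. The cause was not tested. None of the camera calls hold with an estimated correlation in the fits of all libraries in which it was run; it was not run on the fits that leave libraries out. Among values of named genes 1756 kept direction and call, 61 gained a call, 1 lost it and 75 uncalled ones changed sign, and among values of lists 75 kept direction and call and 37 lost the call; camera's direction turned in none, but the median of the cell cycle list was 0.02 without GFP replicate 4, against -0.14. At this depth and spread 11394 of 15150 genes had an interval within 2-fold, and for the others a change of 2-fold or more is not excluded.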

Other observations

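The tests with the GC and length trend removed, in females alone and without both male Has2 libraries were chosen only after the results were seen; the other tests are those of the report.

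Of the lists of other gene groups in this paragraph 0 were called. Markers of resting fibroblasts had a median log2 fold change of -0.06 over 19 genes (camera adjusted p = 0.623), but the surface antigen Ly6a, which interferon also induces, was at 269 ± 23.4 CPM with the GFP virus and 177 ± 37.5 CPM with the Has2 virus (SD, n = 4; log2 fold change -0.60, SE 0.16), lower in 4 of 4 pairs and the 1 member called over the list alone with the replicate block. Genes of TGF-beta signalling had a median of 0.07 over 33 genes (camera adjusted p = 0.285), with the repressor Ski at 0.21 (SE 0.12; 0.12 with the GC and length trend removed) and the receptor Tgfbr1 at -0.47 (SE 0.36; 0.12 in female and -1.28 in male pairs, 0.02 without both male Has2 libraries, and -0.89 to -0.24 when single libraries or replicates were left out). Proteoglycans had a median of 0.06 over 21 genes (camera adjusted p = 0.45), with lubricin (Prg4) at 0.50 (SE 0.22), perlecan (Hspg2) at 0.30 (SE 0.14; 0.17 with that trend removed) and biglycan (Bgn) at 0.32 (SE 0.21), each higher in 4 of 4 pairs. The collagenase Mmp13 was low, at 1.70 ± 0.60 and 3.75 ± 1.14 CPM with the GFP and Has2 viruses (SD, n = 4; log2 fold change 1.14, SE 0.33), and higher in 4 of 4 pairs. Among heat shock genes (13 measured, median 0.01, camera adjusted p = 0.38) Hspa1b had a log2 fold change of 0.60 (SE 0.28), the 1 member called over the list alone with the replicate block, and Cryab one of 0.25 (SE 0.12).

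Genes of oxidative phosphorylation had a median of -0.05 over 35 members (camera adjusted p = 0.154), with Cox7b at -0.52 (SE 0.15) and Atp5f1 at -0.35 (SE 0.14), and ribosomal proteins one of -0.07 over 40 (camera adjusted p = 0.154), with Rpl7 at -0.37 (SE 0.17) and Rpl5 at -0.28 (SE 0.13). These 4 genes were lower in 4 of 4 pairs, but with the GC and length trend removed Cox7b was at -0.14, Atp5f1 at 0.16, Rpl7 at -0.15 and Rpl5 at 0.02, and without Has2 replicate 1 Rpl7 was at -0.23. The macrophage markers Cd68 (log2 fold change 0.29, SE 0.38; 0.08 to 0.54 when single libraries or replicates were left out) and Ptprc (-0.49, SE 0.58; 0.02 in females alone, -0.17 with the trend removed, and -1.07 to -0.22 when single libraries or replicates were left out) were measured at 52.7 and 13.8 CPM on average, and macrophage genes did not pass as a list (camera adjusted p = 0.753). Mitochondrially encoded transcripts held 0.417% to 1.88% of the counts, lowest in Has2 replicate 3 and highest in Has2 replicate 1.

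Transcripts of the sex chromosomes matched the labels. Xist was at 52.5 to 163 CPM in the female libraries and had 0 to 5 counts in the male ones. The Y-linked Ddx3y was at 46.3 and 50.8 CPM in the male GFP libraries but at 15.1 and 17.7 CPM in the male Has2 libraries, and Eif2s3y at 50.5 and 42.0 against 18.1 and 17.99 CPM, while Kdm5d differed less (12.99 and 13.1 against 9.34 and 8.59 CPM). Uty, the other Y-linked gene checked, was at 10.2 and 12.9 against 4.09 and 5.23 CPM. The longest transcripts of Ddx3y, Eif2s3y and Kdm5d have GC contents of 36.1%, 36.4% and 43.8%. Over the 4 Y-linked genes the median log2 fold change of the main fit was -1.34, and -0.35 with the GC and length trend removed. In GFP replicate 1, from a female, Ddx3y had 12 counts, Eif2s3y 18 and Kdm5d 1, where the other female libraries had 0.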
